A study of Drosophila melanogaster with 3 samples.

How the data were processed

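RNA fragments bound by the exon junction complex (EJC) were sequenced from S2 cells, an established Drosophila melanogaster line with hemocyte-like properties. The EJC is a protein complex left on mRNA by splicing, with eIF4AIII, Y14 and Btz (Barentsz) among its core proteins. Per the labels' protocols, the cells carried a copper-inducible tagged protein, were grown for 72 h and received 100 µg/ml cycloheximide for 2 h, which blocks translation and so the removal of the complex by ribosomes. Complexes were captured by the tag, selected on oligo(dT), trimmed with micrococcal nuclease (MNase) and captured again with an antibody against a second, endogenous EJC protein. The 3 libraries were tagged eIF4AIII followed by Y14, tagged Btz followed by eIF4AIII, and tagged Y14 followed by eIF4AIII, written below as eIF4AIII/Y14, Btz/eIF4AIII and Y14/eIF4AIII. MNase was used at 0.5 units for the first 2 and at 0.3 units for Y14/eIF4AIII, for 15 min each. Each purification had 1 library, so no difference between purifications could be tested and no p-value is given. No control purification was analysed here.

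The authors deposited 1 stranded peak list per library, and per the file headers the track names hold the words clipped and merged. Bowtie and SAMtools are named in the submitters' processing notes, without versions or roles. The peak caller, its threshold and the genome build are not given in the sources used here. The deposited score of a peak is a signal value. Multiplied by the peak width it gave a whole number (tolerance 0.001) for 100% of the peaks of each list, as a mean read depth per base would, and it is called depth below. It is not scaled to library size, and the number of reads per library is not given in the sources used here. Scores were used to describe, rank or filter peaks within a list, apart from the ranking of loci and the rank correlation of depth described below. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals over peaks or gaps. They cover counting error only, since each purification had 1 library, and they treat peaks or gaps as independent. PCR copies of a fragment cannot be recognised without molecular identifiers. The name of the track in the eIF4AIII/Y14 list mentions only Y14, and the sample was grouped by its label.

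The sequence names in the lists (among them 2LHet, 3RHet and Uextra) are those of release 5 of the Drosophila genome. The annotation used here is of release 6 (Ensembl 115), so peaks were not assigned to genes, exons or annotated junctions, and the comparisons of annotated junctions and of genes without introns, the counts for gene lists and the values of single genes that had been fixed beforehand were not run. From the annotation only the lengths of introns and their number per chromosome were taken. Coordinates below are release 5 by sequence names, 1-based.

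Lists were compared by overlap of at least 1 bp on the same strand. The background was measured in 3 ways. Each peak was placed at random within its chromosome, between the first and the last peak of any list (1000 placements), each peak was moved by 200 to 1000 nt in a random direction (1000 times), or the strand of each peak was exchanged. Overlapping peaks of the 3 lists were merged into loci. To test how often 1 list was found at loci of the other lists, loci were merged from those other lists alone and ranked by depth per base, multiplied over both lists. A locus counted when its middle base held a peak of the list tested. Widths were made equal between depth classes by weighting 10 classes of width alike in each. Peaks were counted in windows of 10 kb. After adding 0.5, each count was divided by the number of peaks of its list in all windows and taken as log2. An excess in 1 list was set at 4-fold over the mean of these log2 shares in the other lists, with at least 5 peaks, so counts in the shorter list weigh more. Places named in the text are the 10 windows with the most loci found in all 3 lists, up to 5 windows of largest excess per list and the 3 deepest peaks of each list. This rule, the overlap, the placement within chromosomes and the thresholds were chosen before the data were examined. The move by 200 to 1000 nt, the exchange of strands, the measurement of whole-number depth, the depth classes and all measurements of gaps were chosen afterwards.

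A gap is the stretch between neighbouring peaks on 1 strand. Gaps were called shared between lists when both borders were identical. Upstream and downstream follow the strand column of the lists, taken as the strand of the RNA. For each list, the percent of gaps shared by the other lists (up to 2000 nt long) that had a peak of the list itself was measured at every position from 100 nt upstream to 100 nt downstream, so that the list measured had no part in choosing the gaps. The overlap, merging and gap functions were tested on simulated data. Random placement of the 5938 eIF4AIII/Y14 peaks of 2L gave an overlap of 1.34%, against 1.35% calculated from the widths. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were the upper part of each list by depth (at or above its median), reciprocal overlap of 50%, no regard to strand, lists of equal length, another constant in the windows, the main chromosome arms alone, and lists without peaks of whole-number depth.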

Results

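Peak lists of 3 tandem purifications of the exon junction complex from S2 cells were compared. The eIF4AIII/Y14 list held 34945 peaks, the Btz/eIF4AIII list 36393 and the Y14/eIF4AIII list 16094, with 1 library each. The peaks covered 1235 kb, 2242 kb and 853 kb of sequence, at a mean depth over the covered bases of 159, 292 and 371 reads. Median peak widths were 31 nt, 53 nt and 48 nt in the same order, with 0.5 units of MNase for the first 2 and 0.3 units for Y14/eIF4AIII. Median depths per peak were 52, 95.3 and 34 reads per base. The 100 peaks with the largest summed depth held 15.1%, 16.95% and 18.7% of all depth.

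The peaks lay almost entirely on the main chromosome arms. The small chromosome 4 carried 1.77% of the eIF4AIII/Y14 peaks (95% interval 1.63 to 1.91), 1.63% of the Btz/eIF4AIII peaks (1.51 to 1.77) and 1.43% of the Y14/eIF4AIII peaks (1.25 to 1.62). Between its first and last peak it held 488, 470 and 182 peaks per Mb in the same order, against 363, 373 and 159 per Mb on 2R, the densest of the large arms in each list. Heterochromatic sequences held 0.549%, 0.525% and 0.659% of the peaks. The unplaced sequences U and Uextra held 0.498% and 0.844% of the eIF4AIII/Y14 and Btz/eIF4AIII peaks and 2.81% of the Y14/eIF4AIII peaks (2.56 to 3.08). The mitochondrial genome, whose genes have no introns, held 1 of the 36393 Btz/eIF4AIII peaks. It held 0 of the 34945 eIF4AIII/Y14 peaks and 0 of the 16094 Y14/eIF4AIII peaks. The lists hold called peaks alone, so RNA below the calling threshold would not appear, and whether mitochondrial reads were removed before peak calling is not stated in the sources used here.

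The first comparison asked how far the 3 purifications mark the same places. The eIF4AIII/Y14 and Y14/eIF4AIII purifications go through the same pair of EJC proteins in reversed order. Only Btz/eIF4AIII goes through another pair. Of the eIF4AIII/Y14 peaks, 41.8% (95% interval 41.3 to 42.3) overlapped a Btz/eIF4AIII peak. Of the Y14/eIF4AIII peaks, 44.8% (43.99 to 45.5) overlapped a Btz/eIF4AIII peak and 35.1% (34.4 to 35.8) an eIF4AIII/Y14 peak. In the other direction 37.9% of the Btz/eIF4AIII peaks overlapped an eIF4AIII/Y14 peak and 19.3% a Y14/eIF4AIII peak, and 16.7% of the eIF4AIII/Y14 peaks overlapped a Y14/eIF4AIII peak. Peaks placed at random within their chromosomes overlapped in 0.567% to 1.62% of cases (medians over 1000 placements), and overlap with peaks of the opposite strand ran from 0.448% to 1.19%. Peaks moved by 200 to 1000 nt, which leaves most of them in the same neighbourhood, overlapped in 7.77% to 20.4% of cases. The observed overlaps were 2.15 to 2.50 times these values and lay above all 1000 moved sets for each pair.

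**Figure D1:**
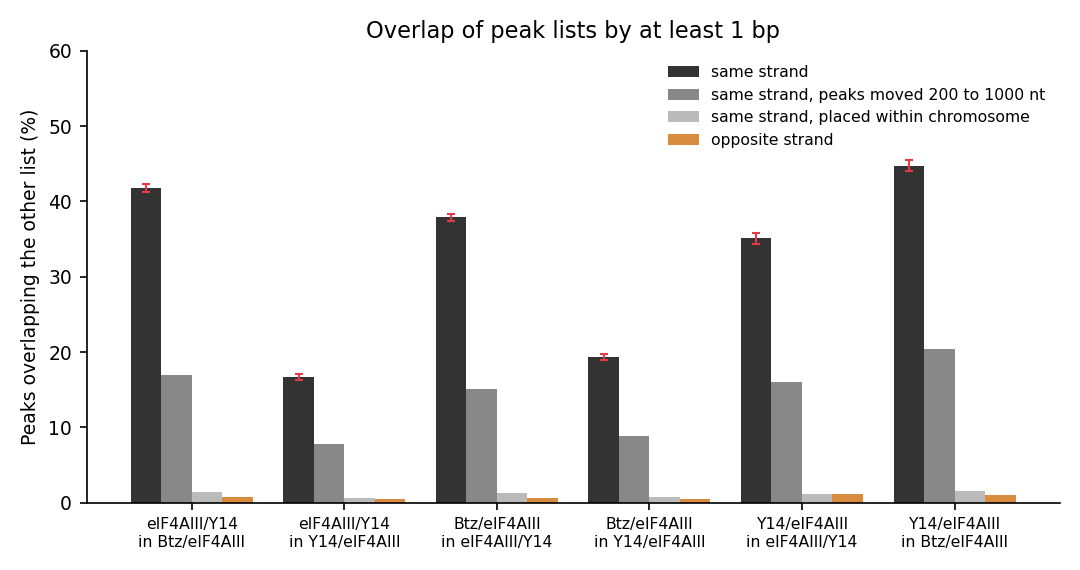
Percent of the peaks of 1 list (first name) that overlap a peak of another (second name) by at least 1 bp; dark bars are observed values with exact 95% binomial intervals in red (counting error), and the other bars are the medians of moved and of randomly placed peaks and the overlap with the opposite strand. For the first pair 41.8% overlapped on the same strand and 0.738% on the opposite strand.

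The 3 lists merged into 63358 loci. Most of these, 45647 or 72.0%, had a peak in a single list, 13451 (21.2%) in 2 lists, and 4260 (6.72%; 95% interval 6.53 to 6.92) in all 3. Random placement within chromosomes gave a median of 7 loci in all 3 lists (range 1 to 16), and moving the peaks by 200 to 1000 nt gave 1002 (range 922 to 1078). Loci of eIF4AIII/Y14 and Btz/eIF4AIII without Y14/eIF4AIII numbered 9351, those of Btz/eIF4AIII and Y14/eIF4AIII 2565, and those of eIF4AIII/Y14 and Y14/eIF4AIII 1535. The lists differ in length, which bears on these numbers. With each list reduced to its 16094 deepest peaks, 25.7% of the eIF4AIII/Y14 peaks overlapped Btz/eIF4AIII, 24.8% of the Y14/eIF4AIII peaks overlapped Btz/eIF4AIII and 19.6% overlapped eIF4AIII/Y14. In the other direction, 24.8% of the Btz/eIF4AIII peaks overlapped eIF4AIII/Y14 and 23.3% overlapped Y14/eIF4AIII. Of the eIF4AIII/Y14 peaks, 19.5% overlapped Y14/eIF4AIII. At this length the lists made through the same pair of proteins thus overlapped least, with 1 library each. Peak widths were not made equal in this comparison, and wider peaks overlap more easily. In the full lists, this pair overlapped 2.15 and 2.19 times as often as moved peaks. The values were 2.18 and 2.19 for Btz/eIF4AIII with Y14/eIF4AIII, and 2.46 and 2.50 for eIF4AIII/Y14 with Btz/eIF4AIII. The count of loci in all 3 lists was 1625 with 16094 peaks per list (4.24% of the loci). It was 1602 in the full lists when overlap had to reach 50% of both peaks (2.13%).

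Deeper peaks were found again more often, though they were also wider, which by itself raises an overlap of 1 bp. In the eIF4AIII/Y14 list, 37.6% of the peaks in the lowest of 4 depth classes of equal size overlapped either other list (95% interval 36.6 to 38.6), against 61.0% in the highest (59.98 to 62.04). The same shares were 37.99% and 53.7% for Btz/eIF4AIII and 42.6% and 62.5% for Y14/eIF4AIII. From the lowest to the highest class the median width went from 29 to 33 nt in eIF4AIII/Y14, from 36 to 63 nt in Btz/eIF4AIII and from 28 to 61 nt in Y14/eIF4AIII. With widths made equal between the classes, the shares were 39.4% and 59.2%, 41.97% and 54.3%, and 52.1% and 70.5%. When the middle base of the peak had to be covered, they were 32.5% and 56.5% for eIF4AIII/Y14, 30.5% and 37.9% for Btz/eIF4AIII, and 36.1% and 49.3% for Y14/eIF4AIII. The class below the highest then had 29.2% in Btz/eIF4AIII and 49.4% in Y14/eIF4AIII, so the rise was not steady in these lists. With widths also made equal, the middle-base shares by class were 41.7%, 47.5%, 54.6% and 60.1% in Y14/eIF4AIII, a steady rise. In Btz/eIF4AIII they were 29.5%, 31.9%, 31.0% and 39.5%, still not steady.

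**Figure D2:**
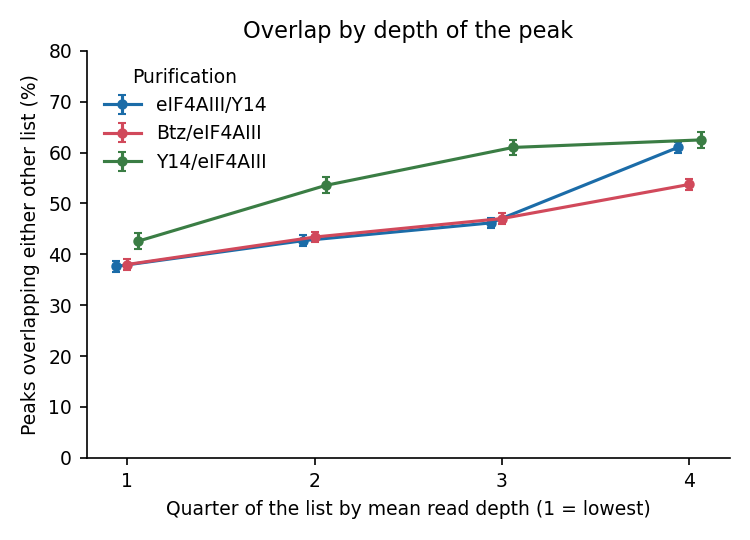
Percent of peaks overlapping either other list (vertical axis) in each of 4 classes of a list by mean read depth, lowest to highest (horizontal axis), 1 line per purification, with exact 95% binomial intervals over peaks. All 3 lines rise, from 37.6% to 61.0% for eIF4AIII/Y14.

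The densest clusters of loci shared by all 3 lists lay in neighbouring windows of 10 kb on 3L. Window 500001 to 510000 held 29 such loci, from 59 eIF4AIII/Y14, 38 Btz/eIF4AIII and 47 Y14/eIF4AIII peaks, and window 490001 to 500000 held 27. The next were 3L 6200001 to 6210000 with 17 loci, 2L 8220001 to 8230000 with 16, chromosome 4 670001 to 680000 with 15 and 2L 210001 to 220000 with 14. The windows at 3L 5750001 and 2L 5010001 held 13 each, and those at 2R 13580001 and 2R 13410001 held 12 each. Of 7005 windows with a peak, 1898 held a locus found in all 3 lists.

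The 3 deepest peaks of each list all had a counterpart in both other lists, by at least 1 bp. The ranks of these counterparts in their own lists ran from 1 to 26058. The lowest, in eIF4AIII/Y14, had 0.35 times the median depth of its list. Over the 4260 loci in all 3 lists, summed depth was only weakly rank-correlated between lists (a measure chosen afterwards). Spearman coefficients were 0.21 for eIF4AIII/Y14 with Btz/eIF4AIII, 0.15 for eIF4AIII/Y14 with Y14/eIF4AIII and 0.29 for Btz/eIF4AIII with Y14/eIF4AIII. Depths are the authors' values for each library and are not scaled between libraries, so they describe a peak within its own list. On 2R, the peak at 13504260 to 13504428 on the plus strand was the deepest of the Btz/eIF4AIII list at 68646 reads per base. The overlapping peak ranked 3 in Y14/eIF4AIII at 28069 reads and 51 in eIF4AIII/Y14 at 4040 reads. The deepest eIF4AIII/Y14 peak, on chromosome 4 at 964178 to 964203, plus strand, had 33038 reads per base and overlapped a Btz/eIF4AIII peak of 9567 reads and a Y14/eIF4AIII peak of 116 reads. The next, on the unplaced sequence U at 5771681 to 5771731, minus strand, had 25725 reads against 70.9 and 49.9 in Btz/eIF4AIII and Y14/eIF4AIII. The peak ranked 3, on 3L at 224113 to 224183, plus strand, had 23666 reads against 2441 and 9412. The deepest Y14/eIF4AIII peak, on 2L at 13211926 to 13212044, minus strand, had 49594 reads against 965 in eIF4AIII/Y14 and 5547 in Btz/eIF4AIII. Its second, on 2R at 7780626 to 7780688, plus strand, had 32250 reads against 368 and 1923. In the Btz/eIF4AIII list the peaks ranked 2 and 3 were on 3L at 831869 to 832010, minus strand, with 58866 reads, and on X at 3679473 to 3679528, plus strand, with 41580 reads. There eIF4AIII/Y14 had 203 and 18.2 reads and Y14/eIF4AIII 9188 and 4982.

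The second comparison asked whether any part of the genome was marked in 1 purification far more than in the others. An excess of peaks passed the rule of size in 53 windows for eIF4AIII/Y14, 78 for Btz/eIF4AIII and 15 for Y14/eIF4AIII. When the peaks of all windows were dealt to the lists at random 100 times, the rule was passed by a median of 37, 38 and 18 windows and by at most 56, 56 and 31. Only the Btz/eIF4AIII count lay above all random deals. With a constant of 1 added in place of 0.5 it was 17, for which no random deals are available. The deals treated the peaks of a window as independent, which runs of peaks on 1 strand, as in the leading windows below, need not be. The leading Btz/eIF4AIII windows were next to each other on chromosome 4. Together 540001 to 560000 held 37 Btz/eIF4AIII peaks, all on the plus strand between 542105 and 559312, against 1 eIF4AIII/Y14 peak and 0 Y14/eIF4AIII peaks. The window at 2L 14320001 held 28 Btz/eIF4AIII peaks, all on the plus strand, against 3 and 0. The median depth of the Btz/eIF4AIII peaks was 32.7 reads per base in the chromosome 4 windows and 31.0 in the 2L window, against 95.3 for the whole list. The strands and depths in these windows were examined after their counts were seen. The windows 2L 16440001 and 2R 10180001 held 10 each against 0 in both other lists. For eIF4AIII/Y14, the leading windows were 2R 5300001 with 10 peaks, 3R 12450001 with 8, X 13110001 with 7, and 2L 6010001 and 2L 17510001 with 5 each, none with a peak in the other lists. For Y14/eIF4AIII, 3L 8980001 held 8 peaks against 1 in eIF4AIII/Y14 and 2 in Btz/eIF4AIII, and 2R 13740001 held 6 against 0 and 3. Windows 2L 20960001, 3R 22270001 and 3R 7380001 held 5 each, against 2, 3 and 0 in eIF4AIII/Y14 and 0, 0 and 4 in Btz/eIF4AIII.

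The series concerns splice junctions, and since junctions could not be placed on these coordinates, the spacing of peaks was measured instead. Gaps between neighbouring peaks of 1 strand had their modal length at 60 nt in all 3 lists, after smoothing over 5 nt. Gaps of 50 to 75 nt numbered 3497 in eIF4AIII/Y14, 6288 in Btz/eIF4AIII and 1154 in Y14/eIF4AIII. This was 134.5, 242 and 44.4 gaps per nt of length, against 69.0, 81.1 and 20.6 per nt for gaps of 76 to 99 nt and 81.4, 94.3 and 26.2 per nt for gaps of 25 to 49 nt. Many of these gaps had the same borders in different libraries, to the base. Both borders of 28.1% of the eIF4AIII/Y14 gaps of 50 to 75 nt (981 gaps; 95% interval 26.6 to 29.6) recurred in Btz/eIF4AIII, against 0.639% of those of 25 to 49 nt and 2.53% of those of 100 to 200 nt. Shared with Y14/eIF4AIII were 5.63% of the eIF4AIII/Y14 gaps and 5.66% of the Btz/eIF4AIII gaps of 50 to 75 nt. In the upper part of each list by depth the 3 shares fell to 21.99%, 3.55% and 4.71%. With one list moved by 5 to 25 nt, at most 0.00136% of the gaps of 50 to 75 nt shared both borders. In all, 1998 gaps were shared by at least 2 lists, 61.7% of them of 50 to 75 nt, and 230 were in all 3.

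**Figure D3:**
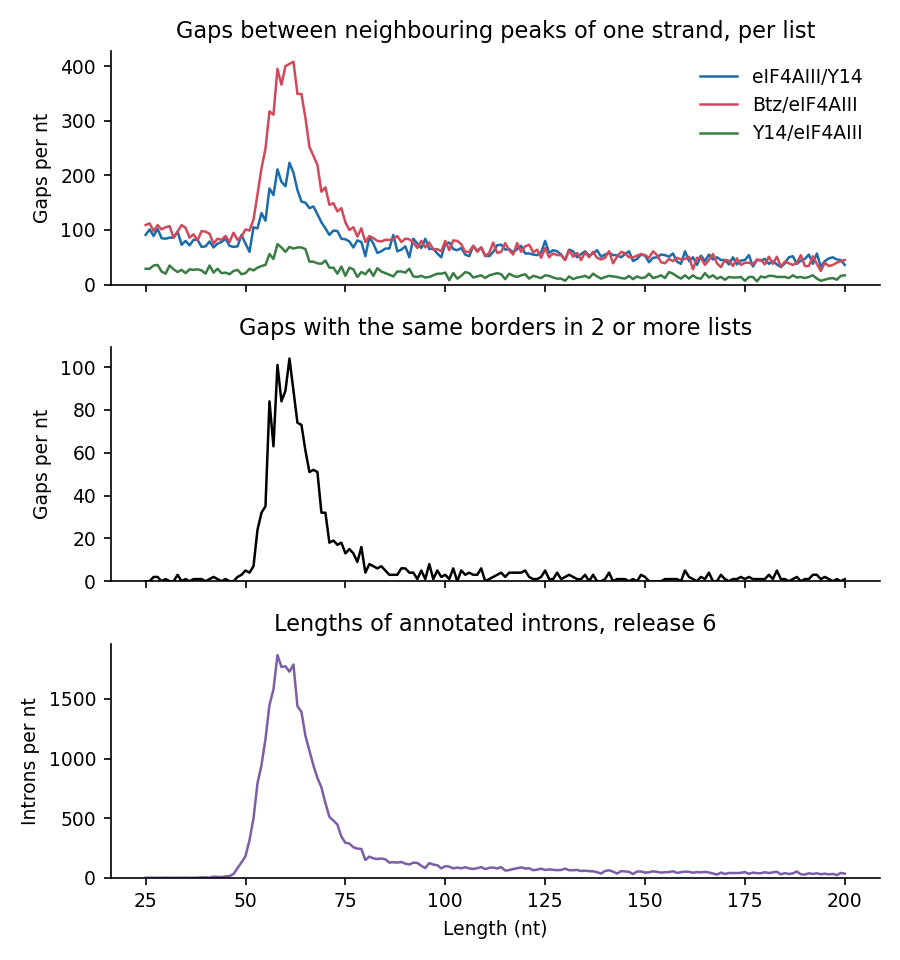
Number of gaps between neighbouring peaks per nt of gap length for the 3 lists (top), number of gaps with identical borders in 2 or more lists (middle) and number of distinct introns in the release 6 annotation (bottom), all by length in nt from 25 to 200. Every curve has its mode at 60 nt after smoothing over 5 nt.

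Beside gaps shared by the other lists, peaks of each list more often covered the base 22 nt upstream than the base 22 nt downstream, while at the borders themselves coverage was closer. Of 560 gaps shared by Btz/eIF4AIII and Y14/eIF4AIII, 80.2% (95% interval 76.6 to 83.4) had that base covered by an eIF4AIII/Y14 peak upstream and 26.25% (22.65 to 30.1) downstream. Of 296 gaps shared by eIF4AIII/Y14 and Y14/eIF4AIII, 82.4% (77.6 to 86.6) had a Btz/eIF4AIII peak upstream and 60.8% (55.0 to 66.4) downstream. Of 1469 gaps shared by eIF4AIII/Y14 and Btz/eIF4AIII, 27.6% (25.4 to 30.0) had a Y14/eIF4AIII peak upstream and 15.5% (13.7 to 17.5) downstream. Where only 1 of these bases was covered, it was the upstream base at 321 of 340 gaps, 71 of 78 and 281 of 384, respectively. At the base next to the gap the values were 52.9% upstream and 48.0% downstream for eIF4AIII/Y14, 81.8% and 80.1% for Btz/eIF4AIII and 26.1% and 22.7% for Y14/eIF4AIII. When any base of a peak within 50 nt of the border counted, they were 83.6% and 59.3%, 86.5% and 85.1%, and 33.6% and 29.0%. In Btz/eIF4AIII the sides thus differed in how far the peaks reached, with 1.35 percentage points between them in the presence of a peak. Coverage upstream was highest at 28 and 26 nt in eIF4AIII/Y14 (80.9%) and at 13 nt in Y14/eIF4AIII (28.5%). In Btz/eIF4AIII it was highest from 13 to 10 nt and at 7 nt (83.8%), and stayed at 81.8% or more up to the border. Downstream it was highest at 1 nt in each list. The eIF4AIII/Y14 peaks stayed above 50% of their highest value from 50 nt upstream to 5 nt downstream. For Btz/eIF4AIII this range ran from 71 nt upstream to 65 nt downstream, and for Y14/eIF4AIII from 52 nt upstream to 32 nt downstream. At 80 nt the values were 19.1% upstream and 20.9% downstream for eIF4AIII/Y14, 37.5% and 33.4% for Btz/eIF4AIII and 10.3% and 10.6% for Y14/eIF4AIII. The middle of the gap held a peak of the list left out in 2.86%, 1.69% and 3.54% of cases.

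Gaps of 100 to 200 nt of 1 other list that were not shared served as background, so that their length, their sharing and their source all differ from the gaps above. Beside Btz/eIF4AIII gaps, eIF4AIII/Y14 peaks were found at 26.5% upstream and 24.6% downstream. Beside eIF4AIII/Y14 gaps, Btz/eIF4AIII peaks were found at 39.1% and 42.9%, and Y14/eIF4AIII peaks at 14.5% and 15.8%. For gaps of all lengths to 2000 nt that were not shared, from either other list, upstream minus downstream ran from -2.71 to 8.78 percentage points. For those of 50 to 75 nt it ran from -0.636 to 34.6, the highest being eIF4AIII/Y14 beside Btz/eIF4AIII gaps. Of the gaps found in all 3 lists, the 2 whose least deep peak was deepest are given as examples, chosen after the values were seen. The first lies on 2L at 156553 to 156735, plus strand, and is 183 nt long. The peaks upstream and downstream of it had 2745 and 966 reads per base in eIF4AIII/Y14, 1870 and 896 in Btz/eIF4AIII and 553 and 489.6 in Y14/eIF4AIII. The other lies on 3L at 23319057 to 23319787, minus strand, and is 731 nt long. Its peaks had 3841 reads per base upstream and 469 downstream in eIF4AIII/Y14 and 1074 and 596 in Y14/eIF4AIII, whereas in Btz/eIF4AIII the downstream peak was deeper, with 2202 reads against 1939. Over the 230 gaps in all 3 lists, depth was higher upstream at 172 and downstream at 52 in eIF4AIII/Y14, at 141 and 81 in Btz/eIF4AIII and at 97 and 68 in Y14/eIF4AIII, with identical deposited values (no tolerance) at the others. The median widths of the upstream and downstream peaks were 48 and 13.5 nt in eIF4AIII/Y14, 64 and 44 nt in Btz/eIF4AIII and 39 and 21.5 nt in Y14/eIF4AIII.

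**Figure D4:**
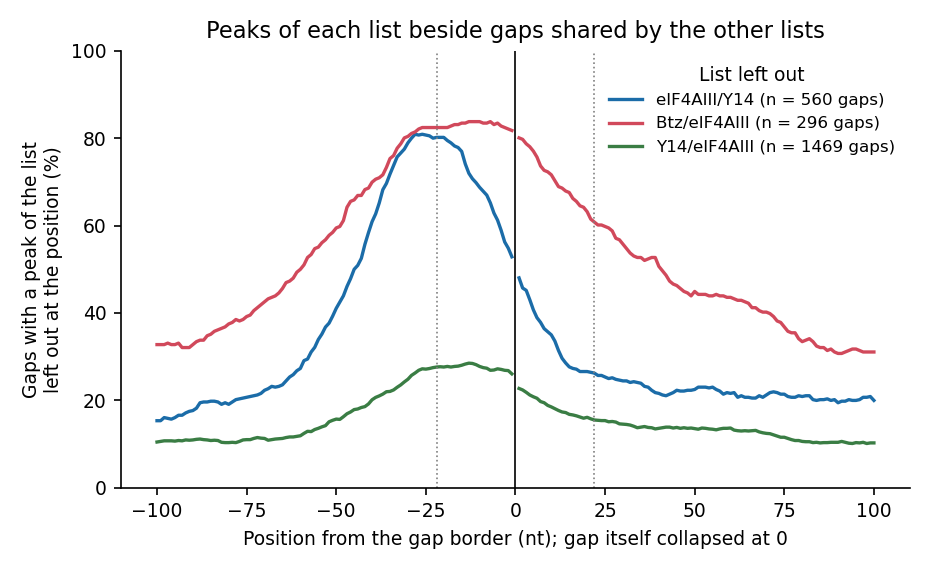
Percent of gaps shared by 2 lists that have a peak of the list left out (vertical axis) at each position in nt from the gap border (horizontal axis, negative is upstream by the strand column, gap collapsed at 0). Dotted lines mark 22 nt on either side; eIF4AIII/Y14 reaches 80.2% upstream and 26.25% downstream there.

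A large part of the peaks had a depth that was a whole number (tolerance 1e-09). Among peaks of at least 15 nt this was so for 51.7% in eIF4AIII/Y14 (95% interval 51.2 to 52.3), 39.1% in Btz/eIF4AIII (38.6 to 39.6) and 53.3% in Y14/eIF4AIII (52.5 to 54.1), against 3.29%, 2.12% and 2.46% if the depth sum were unrelated to the width. At depths of 500 or more the share was 2.27% in eIF4AIII/Y14, 18.1% in Btz/eIF4AIII and 28.5% in Y14/eIF4AIII, against 2.41%, 1.85% and 1.70% if unrelated to the width, so the deepest eIF4AIII/Y14 peaks showed no excess. Lists were also compared without peaks of whole-number depth, there of any width. The overlap of eIF4AIII/Y14 with Btz/eIF4AIII was then 49.9%, whereas that of Btz/eIF4AIII fell to 36.6% with eIF4AIII/Y14 and to 16.9% with Y14/eIF4AIII. The count of loci in all 3 lists was 2080, or 6.44% of 32280 merged loci, against 6.72% of 63358 with all peaks.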

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

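The test of whole-number depth was written after the lists had been examined but before its own result was seen, and the match on width was added afterwards. The test of the tagged Y14 list was chosen after an earlier form had been seen. That form gave a larger rise and was dropped, since its ranking favoured wide loci and peaks of the list tested took part in making the loci. The overlap of opposite strands was outside the main comparisons and above the limit that a count of 0 allows. In the eIF4AIII/Y14 list 312 peaks (0.893%) overlapped a peak of the opposite strand of the same list, in Btz/eIF4AIII 214 (0.588%) and in Y14/eIF4AIII 128 (0.795%). That limit is passed by chance in lists of this length. Random placement within chromosomes, added afterwards, gave medians of 1.01%, 1.75% and 0.646% (ranges 0.816 to 1.15, 1.503 to 2.0004 and 0.454 to 0.845), so no list lay above all 1000 placements and Btz/eIF4AIII lay below them.

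Reads stacked on common ends would give a peak a whole-number depth. Among peaks of depth 50 or more, those of whole-number depth overlapped either other list in 30.6% of cases in eIF4AIII/Y14, against 62.8% for other peaks of the same depth. The values were 27.2% against 58.5% in Btz/eIF4AIII and 47.7% against 70.7% in Y14/eIF4AIII, so the ratio was at most 0.67 over the 3 lists. Matched also on width, the ratios were 0.62, 0.52 and 0.73. This is consistent with part of these peaks being copies of single fragments made by amplification. At depths of 500 or more the whole-number share in eIF4AIII/Y14 was 2.27%, against 2.41% by chance. This share cannot decide whether such peaks hold copies, since at high depth a few reads with other ends suffice to remove a whole-number depth. The ratios above cover all peaks of depth 50 or more together. A precise cut by MNase at true sites stays open as a source of common ends, but was not tested, and no biological explanation was tested.

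The Y14/eIF4AIII list was the shortest. Of the loci shared by the other lists, the middle base held a Y14/eIF4AIII peak in 15.6% of the lowest of 4 depth classes (95% interval 14.4 to 16.9) and in 27.3% of the highest (25.8 to 28.8). The rise was 1.75-fold, and 1.68-fold with width made equal. The same rises were 1.17-fold and 1.37-fold for eIF4AIII/Y14 and 1.34-fold and 1.33-fold for Btz/eIF4AIII. These folds start from unlike shares, which limits their comparison between lists. The share went from 33.8% to 39.4% for eIF4AIII/Y14 and from 51.1% to 68.2% for Btz/eIF4AIII, which could not have reached 2-fold. The Y14/eIF4AIII rise lies between the 2-fold set for fewer distinct fragments in the library and the 1.2-fold set against it, so that explanation stays open. The milder digestion (0.3 against 0.5 units of MNase) and the tagged protein itself belong to this library alone, stay open and were not tested apart from it.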

How the results depend on the processing

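The alternatives on the main arms alone, on whole-number depth, on moved peaks, on depth classes and on gaps were chosen after seeing the data. The upper part of each list by depth, which shortens both lists, lowered the overlap of eIF4AIII/Y14 with Btz/eIF4AIII to 28.0%. It lowered that of Y14/eIF4AIII with eIF4AIII/Y14 to 24.3% and with Btz/eIF4AIII to 34.3%. Reciprocal overlap of 50% gave 20.0%, 17.5% and 22.5%, and leaving out whole-number depth gave 49.9%, 36.1% and 50.4%. Leaving out whole-number depth also shortened the lists, to 16315, 21446 and 7292 peaks, against 17560, 18197 and 8070 in the upper part. Shorter lists thus did not always go with lower overlap. Without peaks of whole-number depth the overlap of Btz/eIF4AIII with eIF4AIII/Y14 fell from 37.9% to 36.6% and with Y14/eIF4AIII from 19.3% to 16.9%. That of eIF4AIII/Y14 with Y14/eIF4AIII stayed at 16.8% within its interval. Without regard to strand the overlap of eIF4AIII/Y14 with Btz/eIF4AIII became 42.3%. Loci in all 3 lists numbered 1245 in the upper part, 1602 with reciprocal overlap, 1625 at equal length and 2080 without whole-number depth, against 4260. The total of merged loci also changed, and as shares of it these were 3.55%, 2.13%, 4.24% and 6.44%, against 6.72%. Windows with an excess fell from 53 to 11 (eIF4AIII/Y14) and from 78 to 17 (Btz/eIF4AIII) with a constant of 1; without whole-number depth the eIF4AIII/Y14 count was 28, and in the upper part the Y14/eIF4AIII count was 25 against 15. The rise in peaks found again from the lowest to the highest depth class, 23.4, 15.7 and 19.9 percentage points, became 24.0, 7.41 and 13.1 on the middle base of the peak and 19.7, 12.3 and 18.4 with width made equal. The causes of these moves were not tested. On the main arms alone 12 of 13 values stayed within their interval or 1.5 times their count. Gaps of 50 to 75 nt with shared borders fell in the upper part from 28.1% to 21.99%, from 5.63% to 3.55% and from 5.66% to 4.71%. The share of one-sided borders covered upstream at 22 nt, 94.4%, 91.0% and 73.2%, was lowest at 69.7% (Y14/eIF4AIII without whole-number depth). With any base of a peak within 50 nt it was 90%, 58.3% (95% interval 36.6 to 77.9) and 62.0%. Random placement within the exonic bases of genes was not run, nor were the alternatives for annotated junctions (window, transcript set, peak centre, GC content, exon length), genes without introns and gene lists, since all need gene models of the release of the peaks. No paired analysis was possible because each purification has 1 library. Library depth is unknown, so a locus absent from a list may lie below its detection limit.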

Other observations

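The tests of the modal gap length, of the smallest gap and of unplaceable bases were chosen after the gaps had been seen. Those of shared borders, of depth beside gaps and of the list left out were written before their own results but after the lengths of the gaps had been seen, the last also after depth beside gaps had been seen.

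The X chromosome held a smaller share of peaks than of introns in all 3 lists. Of 60508 distinct introns in the release 6 annotation, those on X made up 16.7% of the introns on the main arms, against 15.3% of the eIF4AIII/Y14 peaks (95% interval 14.9 to 15.7), 15.1% of the Btz/eIF4AIII peaks (14.7 to 15.4) and 15.1% of the Y14/eIF4AIII peaks (14.5 to 15.7). On 2R the share of introns was 21.0% and that of peaks 22.2%, 21.97% and 21.6%. On 3L it was 18.8%, against 19.0%, 19.1% and 20.1% of the peaks. Chromosome 4 had 1.52% of the introns and 1.79%, 1.66% and 1.48% of the peaks. The releases differ in sequence, which was not corrected for. Introns of all annotated genes were counted, and expression was not measured here, so these shares do not give peaks per junction of expressed RNA.

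The hypothesis is that gaps of 50 to 75 nt are short introns crossed by spliced reads. Their modal length of 60 nt differed by 0 nt from that of annotated introns, 43.3% of which are 50 to 75 nt long. Among gaps overlapping a gap of another list, both borders lay within 1 nt at least 5.56 times as often as for gaps of 100 to 200 nt. The tables argue against the authors' merging of peaks, since the mode lay 35 nt above the smallest gap of 25 nt in each list, and against bases on which no read can be placed, since gaps of 25 to 49 nt shared borders at most 0.070 times as often. The track names also hold the word clipped, and the effect of clipping on the borders of peaks was not tested. These tests thus cannot tell whether spliced reads or such processing set the shared borders.

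If the shared gaps are introns, a complex held upstream of the junction would make peaks of a list not used to find them cover more of the upstream side. The excess at 22 nt was 53.9 percentage points for eIF4AIII/Y14, 21.6 for Btz/eIF4AIII and 12.1 for Y14/eIF4AIII, against 1.88, -3.85 and -1.35 beside gaps of 100 to 200 nt of 1 other list that were not shared. In the same order the excess was 49.3, 15.9 and 11.2 points at 15 nt and 54.5, 24.7 and 10.3 points at 30 nt, so 22 nt was not set apart from nearby distances. At the base next to the gap it was only 4.82, 1.69 and 3.34 points, and with any base of a peak within 50 nt it was 24.3, 1.35 and 4.63. Beside unshared gaps of 50 to 75 nt, Y14/eIF4AIII had -0.636 and 2.83 points by source list, Btz/eIF4AIII 7.94 and 5.54, and eIF4AIII/Y14 34.6 and 11.4. These distances and gaps were added after the result at 22 nt had been seen. The excess at 22 nt is consistent with the known position of the EJC, clearest in eIF4AIII/Y14, as a hypothesis that rests on the strand column being the strand of the RNA. Depth gave a weaker answer. Over all gaps of 50 to 75 nt the upstream peak was deeper at 56.6% and the downstream peak at 35.1% in eIF4AIII/Y14, at 52.5% and 36.7% in Btz/eIF4AIII and at 40.7% and 34.7% in Y14/eIF4AIII. At 100 to 200 nt the values were 48.4% and 50.4%, 48.7% and 49.2%, and 49.9% and 46.7%. The test had been set on the median and stays undecided, because the median log2 ratio of upstream to downstream depth over gaps of 50 to 75 nt was 0.40 in eIF4AIII/Y14, 0.01 in Btz/eIF4AIII and 0 in Y14/eIF4AIII, where 24.5% of the gaps had identical deposited values (no tolerance) on both sides.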
